A study of Homo sapiens with 16 samples.

How the data were processed

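CUT&RUN libraries for H3K4me, H3K4me3, H3K27Ac and H3K27me3 were made from G401 cells on days 0, 1, 3 and 7 of doxycycline, 1 library per mark and day, 16 in all. The labels name the antibody target as H3K4me without giving the degree of methylation, and the name is kept here. Per the labels, libraries were sequenced as paired reads of 150 bp at an average of 10 M reads. Per the submitters' processing notes, Bowtie2 and SICER 0.0.41 were used with the human genome build hg19, with no role or setting given for either tool.

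The authors deposited 1 list of 352574 called regions for the whole series, with no header, in which a name column ties each region to a library. Regions were therefore listed per library and not on pooled libraries. The names give the mark and a day for days 1, 3 and 7. The names left over, 1 per mark, start with ND, which was read as no doxycycline and assigned to day 0 by elimination. All rows carried a name that could be assigned.

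The list mixes 2 layouts. For H3K27Ac, H3K4me and H3K27me3 (285195 regions, called islands below) starts lie on a 200 bp grid. The columns hold the reads of the library in the island (21 or more), the reads of a control library, a false discovery rate of at most 0.00134 and the log2 ratio of library reads over scaled control reads (above 1 in all islands). The score column that the authors deposited is 100 times that log2 ratio in these rows, as computed from the values. For H3K4me3 (67379 regions, called peaks below) the layout is that of a narrow peak file, with a fold of 5 or more and a −log10 q of at least 4.40. The tool that made the H3K4me3 peaks is not given in the sources used here. Island ends were read as inclusive. Fold, score and log2 ratio are the authors' values for each region and served to describe or rank regions within 1 library. The log2 ratio also served to recover depth and, at islands matched between days, to compare enrichment over control. The fold of H3K4me3 peaks was also compared between days 0 and 1 in merged regions called on both.

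Sequencing depth was recovered from the island rows. Library reads, control reads and their log2 ratio give the size of the control over that of the library, which lay between 0.632 and 0.789. Islands with 0 control reads were found to use an average of 0.25 control reads. Islands with identical coordinates in the H3K27Ac and H3K4me libraries of the same day had equal control reads in 61.3% of cases (exact 95% interval 53.9% to 68.3%, n = 186). Between different days this share was 11.0% (8.23% to 14.3%, n = 436). On this basis 1 control per day was assumed, although 38.7% of the same-day pairs differed for a reason not known here. For H3K27me3 the assumption could not be checked, because only 2 of its islands shared coordinates with one of these marks on the same day. Control sizes on different days were set against day 0 by the control reads per bp at islands with a reciprocal overlap of at least 80%, pooled over the 3 island marks. This assumes that background per bp did not differ between days at those islands. For day 7 the pooled control size was 1.22 times that of day 0, and H3K27me3 islands alone gave 1.44, which puts the H3K27me3 depth on day 7 at 1.29 where the pooled control puts it at 1.09. The resulting depths against day 0 lay between 0.777 and 1.15. For H3K4me3 the depth is unknown.

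An island of a later day with no base pair shared with an island of day 0 of the same mark was counted as gained, and a day 0 island with none shared with the later day as lost. Observed overlaps were set beside those after 100 random shifts of the islands along their chromosomes, wrapped at the last listed position. Distal, or away from H3K4me3 peaks, means no overlap with an H3K4me3 peak of any day. Signal per region used islands of a mark merged over the 4 days and called on both days compared, with reads divided by the depth and a pseudocount of 1 read. Regions not called on a day carry no read count, so gained and lost islands have no ratio. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Read ratios of named regions are given without an interval, because reads outside the called stretches are not counted. Medians of log2 ratios over control carry bootstrap intervals over islands (1000 draws) where given. With 1 library per mark and day there is no replicate error and no test across days.

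Named regions followed a rule fixed before the data were examined, as were the comparisons and most alternatives. For each mark these are the 5 longest day 7 regions without overlap at day 0, the 5 longest day 0 regions without overlap at day 7, and, where reads are listed, the 10 largest and 10 smallest log2 ratios of day 7 to day 0 among the top 50% of merged regions by mean depth-scaled reads over all days, taken among those called on both days. Coordinates are those of hg19, counted from 1. The gene table supplied belongs to another assembly, so no gene was assigned to a region. The gene lists fixed beforehand and the start site windows of 1 kb and 5 kb were therefore not analysed here.

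The settings varied one at a time were chromosomes 1 to 22 and X alone, merging of islands closer than 1 kb, the stricter 50% of each library by log2 ratio or fold, overlap of at least 50% of the island, overlap within 1 kb, the same number of strongest regions on each day, a pseudocount of 5, scaling by the median ratio or by the top 10% of regions, and the top 50% of regions by mean. Thinning of the deeper library, read density at islands with 80% reciprocal overlap and a depth from each mark's own matched islands were added after the data had been seen. Thinning drew the reads of called islands at random and dropped islands that no longer passed limits on reads, log2 ratio and Poisson probability. Islands were not called again, so shortening, splitting or joining of islands at a lower depth is not covered. The code was tested on simulated data made from the day 0 islands. All 200 gained and 200 lost islands seeded per island mark were found, a true relative depth of 0.8 was recovered as 0.794 for H3K27Ac (10078 islands), 0.804 for H3K4me (26536 islands) and 0.796 for H3K27me3 (16143 islands), and 100% of regions changed 4-fold were called at 2-fold. Between 0.316% (H3K4me) and 0.701% (H3K27me3) of unchanged simulated regions were called at 2-fold. Simulated islands kept their day 0 coordinates or were removed whole, and were not called again. The simulation therefore checks the code and does not cover changes of called length. Its shares are no rate of false calls for the real regions. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.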

Results

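Histone marks were profiled by CUT&RUN, in which an antibody directs a nuclease to release the DNA around marked nucleosomes, in G401 cells. This rhabdoid tumour line lacks SMARCB1, a core subunit of the SWI/SNF chromatin remodelling complex, and here carried a SMARCB1 gene that doxycycline switches on. Cells were sampled on day 0 and after 1, 3 and 7 days with 1 µg/ml doxycycline, with 1 library for each of 4 marks on each day. Every value below therefore lacks a replicate error, and differences between days are given as sizes without a test. All libraries of the later days had doxycycline, so SMARCB1, doxycycline itself and time since day 0 cannot be told apart. Relative to day 0, sequencing depth on days 1, 3 and 7 was 0.852, 1.12 and 1.02 for H3K27Ac, 0.839, 1.03 and 1.08 for H3K4me, and 0.777, 1.15 and 1.09 for H3K27me3. It is unknown for H3K4me3.

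The first comparison asked how much of the genome carried each mark as SMARCB1 was re-expressed. H3K27Ac, a mark of active enhancers and promoters, covered 45.2 Mb in 10078 islands on day 0, and 69.1 Mb in 14853 islands on day 1. It covered 90.7 Mb in 20223 islands on day 3 and 84.1 Mb in 18359 islands on day 7. H3K27me3, the mark laid down by Polycomb repressive complex 2, covered 65.8 Mb on day 0, 30.7 Mb on day 1, 147 Mb on day 3 and 166 Mb on day 7, in 16143, 7974, 34134 and 37966 islands. H3K4me covered 146 Mb on day 0, 120 Mb on day 1, 176 Mb on day 3 and 180 Mb on day 7. H3K4me3, found mainly at promoters, moved least, at 33.2, 28.0, 35.3 and 36.3 Mb on days 0, 1, 3 and 7. More H3K27Ac islands than on day 0 were called on 23 of 23 chromosomes on each later day. For H3K27me3 this held for 0 of 23 chromosomes on day 1 and for 23 of 23 on days 3 and 7. Much of the H3K27me3 difference on day 1 lay within what depth can produce: day 0 held 2.02 times as many islands as day 1, and 1.24 to 1.26 times as many after its reads were thinned to the day 1 depth.

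**Figure D1:**
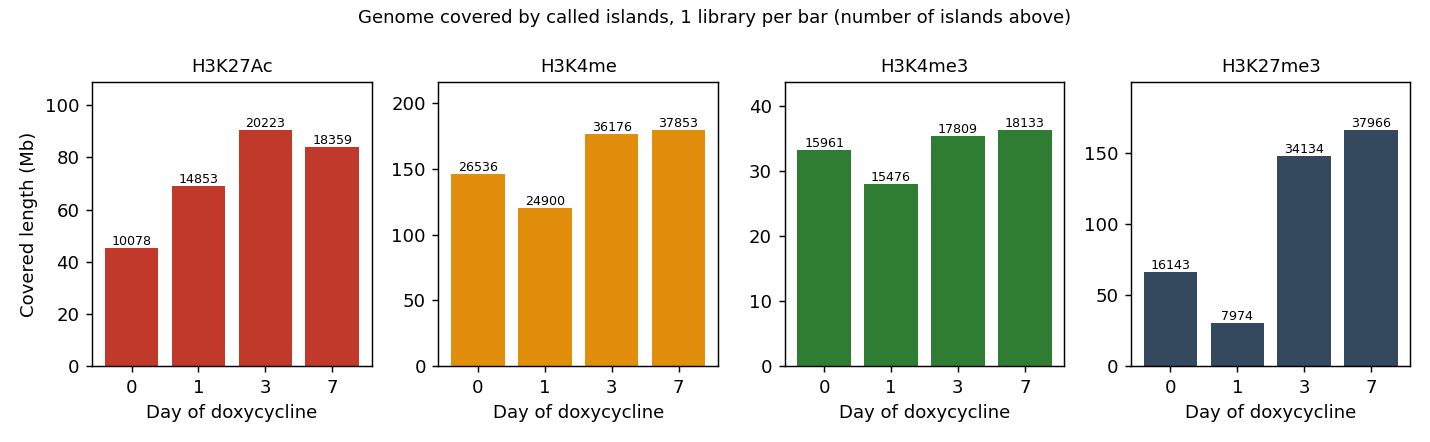
Length of genome in Mb (vertical axis) covered by the called islands of each mark on days 0, 1, 3 and 7 of doxycycline (horizontal axis), with 1 library per bar and the number of islands above it; the vertical range differs between marks. H3K27Ac was above its day 0 length on each later day, and H3K27me3 went from 65.8 Mb to 30.7 Mb on day 1 and 166 Mb on day 7.

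The second comparison asked which islands appeared or disappeared against day 0. H3K27Ac changed mostly by gain, with 9931 islands gained and 917 lost by day 7, so that 54.1% of day 7 islands (95% interval 53.4% to 54.8%) had no counterpart on day 0. Gains were already 6417 on day 1 and were 11673 on day 3, against 1265 and 827 lost. H3K27me3 lost 11173 islands and gained 3064 on day 1, or 6109 and 3996 with day 0 thinned to the day 1 depth. By day 7 it had gained 25106 and lost 3290. Turnover was also high between days 3 and 7, with 14019 H3K27me3 islands gained and 10116 lost. Of 21806 merged H3K27me3 regions absent on day 0 and called on day 7, 11342 were called on day 7 alone. The median H3K27me3 island of day 7 held 35 reads, near the minimum of 21. For H3K4me, 5338 islands were gained and 8590 lost on day 1, but 6181 and 6446 after the same thinning, which leaves little excess of losses. There were 14049 gained and 5044 lost on day 3, and 15354 gained and 4753 lost on day 7. H3K4me3 peaks gained and lost were 915 and 2556 on day 1, 2756 and 1179 on day 3, and 3101 and 944 on day 7. The peaks gained by day 7 were short and weak, with medians of 541 bp and a fold of 6.45. Kept peaks had medians of 1990 bp and 14.5. In 12750 merged H3K4me3 regions called on both days, the fold was lower on day 1 than on day 0, with a median log2 ratio of -0.35. The share of day 7 islands that overlapped day 0 was 45.9% for H3K27Ac, 59.4% for H3K4me, 82.9% for H3K4me3 and 33.9% for H3K27me3, and random shifts gave 3.20%, 8.72%, 2.46% and 4.47%. These counts depend on the number of islands listed: with the same number of strongest H3K27Ac islands on each day, 4299 were gained and 3522 lost by day 7. For H3K27me3 the same setting gave 6441 gained and 6399 lost. Lists of equal number bring gained and lost counts close together by construction, so this setting does not test the excess of gains.

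**Figure D2:**
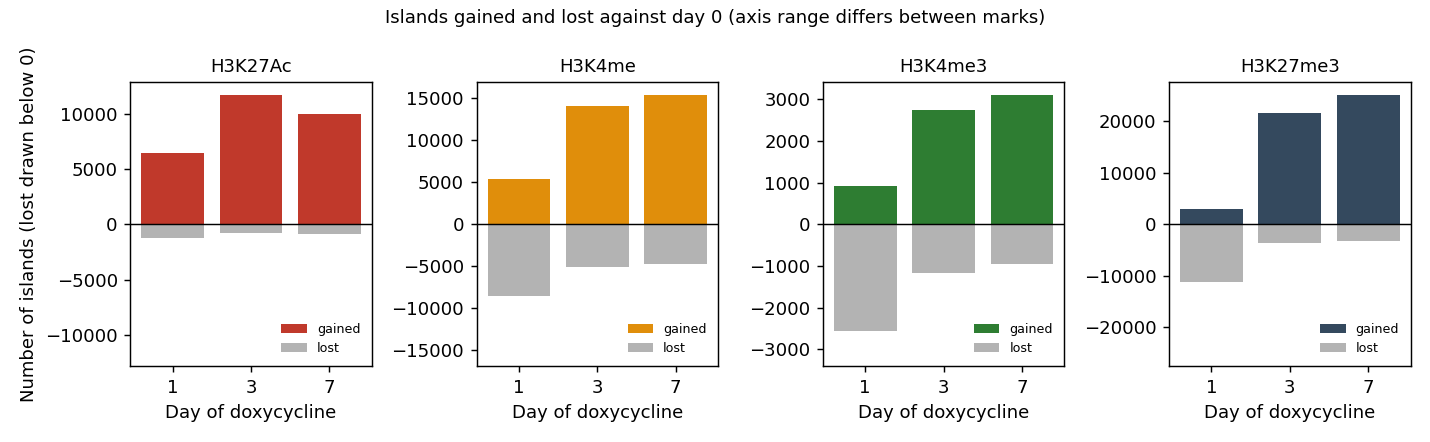
Islands gained (coloured bars, above 0) and lost (grey bars, below 0) against day 0 (vertical axis, number of islands), on days 1, 3 and 7 of doxycycline (horizontal axis), for 1 library per mark and day; the vertical range differs between marks. For H3K27Ac gains exceed losses on each day, while H3K4me, H3K4me3 and H3K27me3 show more losses than gains on day 1 and more gains on days 3 and 7, before any thinning to equal depth; after it H3K4me gained 6181 and lost 6446 on day 1.

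The longest islands new on day 7 gave examples. The longest new H3K27Ac island lay on chromosome 21, 35882601 to 35906000, with 341 reads and a fold over control of 7.48. It was called for H3K27Ac and H3K4me on days 1, 3 and 7, and it contained a new H3K4me3 peak at 35895654 to 35899599, called on days 3 and 7. On chromosome 13, a 29.8 kb H3K4me island at 27540001 to 27569800, called from day 1 on, held an H3K27Ac island at 27551001 to 27569600 that was called on days 3 and 7 and no H3K4me3 peak. Among the other long H3K27Ac gains, those on chromosome 11 (111659001 to 111678000), chromosome 5 (106790201 to 106808400) and chromosome 18 (2972601 to 2989400) carried H3K4me on all 4 days. The 5 longest H3K27me3 gains, such as the 20 kb island on chromosome 5 at 94266001 to 94286000, were called on days 1, 3 and 7 and overlapped no island of the other marks. The longest H3K27Ac island lost by day 7, on chromosome 2 at 232570801 to 232583400, was still called on days 1 and 3 and kept H3K4me and H3K4me3 on every day. The longest lost H3K4me island, on chromosome 1 at 205403601 to 205426200, kept H3K27Ac and H3K4me3 throughout and was called for H3K27me3 on day 7. No gene was assigned to any region.

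The third comparison separated promoter-type regions, those overlapping an H3K4me3 peak of any day, from distal ones, because enhancers lie mostly away from promoters. Distal H3K27Ac islands numbered 2502 on day 0, 5702 on day 1, 9518 on day 3 and 7606 on day 7, so day 7 held 3.04 times the day 0 number. At H3K4me3 peaks there were 7576 H3K27Ac islands on day 0 and 10753 on day 7, 1.42 times as many. The distal share of H3K27Ac was 24.8% on day 0 (24.0% to 25.7%), 38.4% on day 1, 47.1% on day 3 and 41.4% on day 7 (40.7% to 42.1%). Of the H3K27Ac islands gained by day 7, 62.4% (61.4% to 63.3%) were distal, against 16.8% (16.0% to 17.6%) of those kept. The islands lost by day 7 were also mostly distal, at 77.1% (74.2% to 79.8%). H3K4me followed a similar split: distal islands went from 15779 to 17061, 25693 and 26721 on days 0, 1, 3 and 7, while those at H3K4me3 peaks went from 10757 to 7839, 10483 and 11132. H3K27me3 was distal in 96.2% to 98.6% of islands on all days. In the stricter 50% of each library the distal share of H3K27Ac was 35.7% on day 0 and 42.5% on day 7, a smaller gap. The H3K4me3 peaks were cut to their stricter 50% as well. Islands at the weaker peaks then count as distal, unlike in the shares above.

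**Figure D3:**
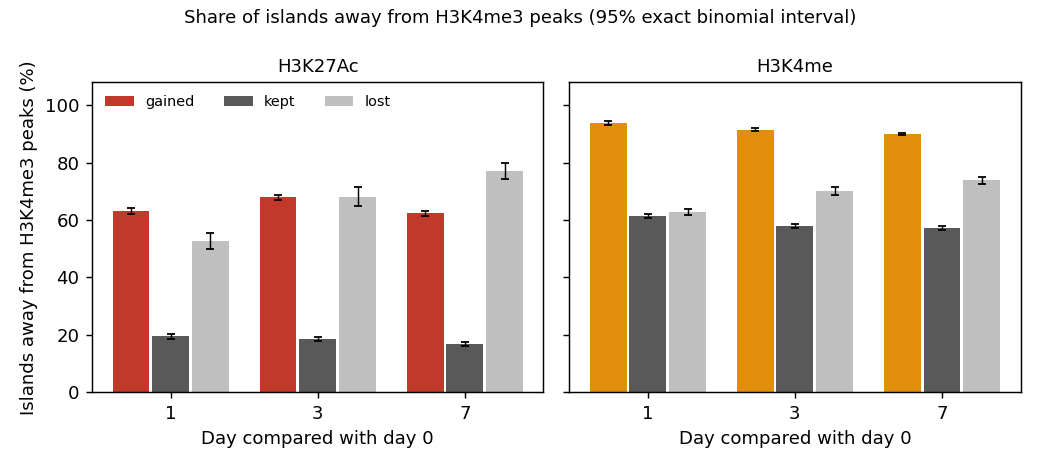
Percent of islands away from H3K4me3 peaks (vertical axis) among H3K27Ac (left) and H3K4me (right) islands gained, kept and lost on days 1, 3 and 7 compared with day 0 (horizontal axis); bars are shares of islands in 1 library and error bars exact 95% binomial intervals. On day 7, 62.4% of gained H3K27Ac islands were distal against 16.8% of kept islands.

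The fourth comparison read chromatin states from marks that overlapped within a day or between day 0 and a later day. Of the H3K27Ac islands gained on day 1, 73.6% (72.5% to 74.7%) overlapped an H3K4me island of day 0, against 85.5% of those kept and 75.1% of those lost. Of the islands gained by day 7, 56.9% (55.9% to 57.9%) did so, against 84.3% of those kept and 84.5% of those lost, so the gained islands lay on day 0 H3K4me less often. On day 7 itself, 82.7% of the islands gained by then overlapped an H3K4me island. Of 14373 distal H3K4me islands without H3K27Ac on day 0, 16.9% carried H3K27Ac on day 1, 25.5% on day 3 and 19.6% on day 7. Of 2382 distal H3K27Ac islands with H3K4me on day 0, 75.9% still carried H3K27Ac on day 1 and 74.0% on day 7, while 97.2% of the 7576 H3K27Ac islands at H3K4me3 peaks did so on day 7. Of 7364 H3K4me3 peaks without H3K27Ac on day 0, 32.1% carried it on day 1, 50.3% on day 3 and 51.1% on day 7. The share of all H3K4me3 peaks with H3K27Ac was 53.9% on day 0, 64.5% on day 1, 75.2% on day 3 and 74.9% on day 7. The share with H3K4me was 65.9% on day 0, 45.0% on day 1, 65.5% on day 3 and 68.7% on day 7.

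Repressive and active marks stayed apart. Of H3K27me3 islands, 0.118% (0.0709% to 0.184%) overlapped H3K27Ac on day 0 and 0.284% (0.233% to 0.343%) on day 7, where random shifts gave 2.74% and 5.09%. Of the 16143 islands with H3K27me3 on day 0, 66 carried H3K27Ac on day 7, and 79.6% (79.0% to 80.2%) still carried H3K27me3. H3K4me3 peaks that also carried H3K27me3, the bivalent combination typical of silent developmental promoters, numbered 294 on day 0, 170 on day 1, 496 on day 3 and 554 on day 7. They made up 1.84%, 1.098%, 2.79% and 3.06% of H3K4me3 peaks, below the 3.18%, 1.49%, 6.62% and 7.43% after random shifts. Of the 294 on day 0, both marks were called at 35.7% (30.2% to 41.5%) on day 1, 72.1% (66.6% to 77.2%) on day 3 and 74.5% (69.1% to 79.4%) on day 7. H3K27Ac was present at 7.82% (5.02% to 11.5%) of them on day 0 and at 18.4% (14.1% to 23.3%) on day 7. Over all H3K4me3 peaks the share with H3K27Ac was 53.9% on day 0 and 74.9% on day 7, so a rise was not particular to the bivalent peaks.

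The fifth comparison measured signal in regions called on both days. Depth-scaled H3K27Ac reads were higher than on day 0, with a median log2 ratio of 0.69 on day 1, 0.71 on day 3 and 0.89 on day 7. On day 7, 3217 of 7656 regions were at or over 2-fold higher and 38 at or over 2-fold lower. The called length grew as well, and the median log2 ratio of reads per kb of called length was 0.58. At the 2263 islands matched between the days by a reciprocal overlap of 80%, the median log2 ratio of read density was 0.72, with 502 islands 2-fold higher and 2 lower. The medians of summed reads at and away from H3K4me3 peaks were 0.89 and 0.85, and those of density at the matched islands 0.73 and 0.53. For H3K27me3 the median log2 ratio was 0.56 on day 7, with 2988 of 10600 regions 2-fold higher and 125 lower, but these sums follow the called length. At the 1363 matched H3K27me3 islands the median was 0.17, with 23 islands 2-fold higher and 0 lower. Reads per kb of called length had a median log2 ratio of 0.14, or -0.09 with a depth taken from the H3K27me3 islands alone, and the median difference of the log2 ratio over control at matched islands was -0.06, so no direction of H3K27me3 density was established. H3K4me had a median log2 ratio of -0.10 on day 7, with 1776 of 18478 regions 2-fold higher and 1397 lower. These ratios rest on the recovered depth. Scaling by the median ratio over regions, which centres them, shifted the day 7 log2 ratios by -0.95 for H3K27Ac, 0.10 for H3K4me and -0.76 for H3K27me3, and turned the medians for H3K27Ac and H3K27me3 to -0.04 and -0.19. It gave 416 H3K27Ac regions 2-fold higher and 464 lower, 762 H3K27me3 regions higher and 1190 lower, and 2053 H3K4me regions higher and 1097 lower. Scaling by the top 10% of regions gave 258 higher and 845 lower for H3K27Ac, 630 and 1446 for H3K27me3, and 2148 and 1005 for H3K4me. These scalings move all regions alike and assume that the typical or the strongest regions did not differ, so they do not test the direction.

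The named regions were picked by the ratio of summed reads, which cover only the stretches called on each day. Reads outside called islands are not listed, so the ratio also follows the called length, and the ratio of reads per kb of called length is given beside it. The largest H3K27Ac ratio was on chromosome 3 at 133179201 to 133200800, with 22 reads over 2.0 kb on day 0 and 511 reads over 15.6 kb on day 7. Its log2 ratio was 4.44 for the sums and 1.54 per kb. The merged H3K4me region overlapping it, 133160801 to 133189600, had 30 reads over 2.4 kb and 595 over 28.0 kb, with log2 ratios of 4.16 and 0.66. The largest H3K4me ratio was at 56850001 to 56912800 on the same chromosome, from 57 reads over 8.0 kb to 3615 reads over 60.2 kb, 5.85 for the sums and 2.97 per kb, and it carried H3K27Ac on days 1, 3 and 7. Control reads over the same stretches went from 9 to 372, so the control shared much of this rise. On chromosome 7 at 47518801 to 47547000, H3K27Ac had 26 reads over 2.2 kb on day 0 and 344 over 26.4 kb on day 7. The log2 ratio of 3.64 for the sums there was 0.11 per kb, so the called length accounts for nearly all of it. The largest H3K27me3 ratio was on chromosome 9 at 79503601 to 79520400, with 21 reads over 2.8 kb on day 0 and 322 over 14.6 kb on day 7, 3.75 for the sums and 1.43 per kb. Control reads there went from 1 to 66, so no rise over control was shown. In the other direction, H3K4me at 3984801 to 3995600 on chromosome 9 had 2951 reads over 9.8 kb on day 0 and 183 over 8.8 kb on day 7, with log2 ratios of -4.11 and -3.96, and H3K27Ac called on all days. Control reads fell there as well, from 116 to 14. The lowest H3K27Ac ratio was on chromosome 22 at 31001201 to 31006000, from 90 reads over 3.2 kb to 22 over 1.2 kb, -2.01 for the sums and -0.65 per kb. None of these ratios is set against the control, whose reads in the called stretches moved in the same direction in each region named here. As the extremes of many regions these ratios are exaggerated by selection.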

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

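The results on H3K27me3 and H3K4me were chosen because these marks, like H3K4me3, stood on opposite sides of their day 0 numbers on day 1 and on day 7. The gain of H3K27Ac, which was above day 0 on each later day, was chosen as a main result. No difference between days was tested, because each is 1 library. H3K27me3 islands on day 1 were 0.494 times and on day 7 2.35 times the day 0 number. H3K4me islands stood at 0.938 times on day 1 and 1.43 times on day 7, but day 0 thinned to the day 1 depth left 23308 to 23397 islands against 24900 on day 1, so after this thinning day 1 was not below day 0. Thinning here and below drops called islands without calling them again, so it may miss part of the effect of depth. H3K4me3 peaks stood at 0.970 times on day 1 and 1.14 times on day 7. In what follows, the tests of enrichment at matched H3K27me3 islands, of H3K27me3 in active chromatin, of H3K27Ac depth, of H3K27Ac enrichment at matched islands, of H3K4me loss and enrichment at and away from H3K4me3 peaks, and all uses of a depth from the mark's own matched islands were chosen after the results they measure had been seen.

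For H3K27me3, the values argue against depth as the cause of the day 7 difference: day 7 islands thinned to the day 0 depth still numbered at least 2.11 times the day 0 islands in 20 draws, and at least 1.74 times with a depth taken from the mark's own matched islands. New day 7 islands falling in active chromatin, as open-chromatin background would, were rare, at 1.31% (1.17% to 1.46%) against 10.4% after random shifts. All listed islands had a log2 ratio over control above 1, which can already leave out such background. The low share does not bear on background of other kinds. The day 1 difference is less clear, since day 0 islands thinned to the day 1 depth numbered 1.24 times the day 1 islands at the lowest, which leaves most of the gap to depth. Weaker enrichment on day 1 cannot be told apart from a loss of the mark: the log2 ratio over control was 0.23 higher on day 1 at the 555 matched islands, but 56.5% of the strongest 25% of day 0 islands were called on day 1, so those matched are a selected few. Variation between libraries and the days of SMARCB1 re-expression both stay open, and those days also differed from day 0 in doxycycline and time.

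For the gain of H3K27Ac, thinning day 7 to the day 0 depth left at least 1.79 times the day 0 number of islands, which argues against depth. Within the strongest 25% of day 7 islands by log2 ratio, new islands exceeded kept ones in distal share by 39.8 percentage points (49.3% against 9.58%), which argues against a day 0 library that only missed weak islands as the whole cause of the distal share. In the stricter 50% of each library the gap was smaller, 50.7% against 27.02%. The H3K4me3 peaks were cut there too, so islands at weaker peaks count as distal and the 2 gaps are not on 1 definition. Weaker enrichment throughout the day 0 library stays open as a cause of the number of new islands: at the 2263 matched islands the log2 ratio over control was 0.72 higher on day 7, and read density was higher both at H3K4me3 peaks (0.73) and away from them (0.53). SMARCB1 re-expression, which cannot be told apart from doxycycline itself or time since day 0, and variation between single libraries also stay open.

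For the lower number of H3K4me islands at H3K4me3 peaks on day 1, the values argue against depth as the whole cause, because day 0 islands thinned to the day 1 depth still overlapped at least 62.5% of day 0 H3K4me3 peaks, against 45.0% of day 1 peaks with H3K4me on day 1. At the 2894 matched islands away from peaks the log2 ratio over control was 0.080 higher on day 1 (bootstrap 95% interval 0.042 to 0.125). The difference was -0.15 (-0.18 to -0.11) at the 2655 matched islands at peaks. Weaker enrichment alike in the whole day 1 library was thus not seen at matched islands. These were called on both days at nearly the same extent, so they cannot show weakening at islands that were lost. The bootstrap intervals cover islands and not differences between libraries. Distal islands also numbered 17061 on day 1 against 15779 on day 0, while those at peaks numbered 7839 against 10757. The share of day 0 islands lost was nonetheless not higher at peaks, at 29.8% against 34.1% away from them, a difference of -4.35 percentage points. Of the 5338 H3K4me islands gained on day 1, 94.0% were distal. The island counts go with a like loss at and away from peaks and gains that were mostly distal. The lost shares were not taken at equal depth. In regions called on both days, the median log2 ratio of depth-scaled reads on day 1 was -0.34 at peaks and 0.008 away from them. For read density at matched islands the medians were -0.19 and 0.12. A loss of islands particular to peaks was not shown, but the median signal of islands still called was lower at peaks and not away from them. Weaker enrichment on day 1, the day itself and variation between single libraries stay open.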

How the results depend on the processing

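Thinning of the deeper library to the depth of the other, read density at islands with 80% reciprocal overlap and a depth from each mark's own matched islands were chosen only after the data had been seen. The other alternatives were set before the data were examined. Of the alternative values for the main comparisons, 183 stayed within the tolerance (1.5 times for a count or ratio, the 95% interval for a share), 62 moved further and 6 changed direction. Of those for other results, 74 stayed, 94 moved and 12 changed direction. The ratios of island number and covered length to day 0 kept their direction and stayed within 1.5 times under the alternatives run for them, except under thinning to equal depth. There the H3K4me number on day 1 turned to 1.07 times day 0, and that of H3K27me3 on day 1 was 0.802 times. Restriction to chromosomes 1 to 22 and X, merging of islands closer than 1 kb, a pseudocount of 5 and the top 50% of regions by mean moved no result beyond the tolerance. No paired analysis was possible because each mark and day is 1 library. Start site windows of 1 kb and 5 kb and the gene lists were not run, for want of a gene annotation of the build used here.

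Gained and lost counts depended most on how many islands are listed. With the same number of strongest islands on each day, H3K27Ac gained 3511 and lost 3035 on day 1, gained 4696 and lost 4049 on day 3, and gained 4299 and lost 3522 on day 7. H3K27me3 gained 5291 and lost 5347 on day 1, gained 6360 and lost 6348 on day 3, and gained 6441 and lost 6399 on day 7. H3K4me gained 9421 and lost 9495 on day 3, and gained 9611 and lost 9571 on day 7. H3K4me3 gained 1544 and lost 1537 on day 3, and gained 1639 and lost 1382 on day 7. In the stricter 50% of each library, where fewer islands are listed, H3K27Ac gained 6762 and lost 1484 on day 3 and gained 6050 and lost 1560 on day 7. H3K27me3 lost 6717 on day 1 and gained 13285 on day 3 and 15067 on day 7, and H3K4me3 gained 1500 on day 1. Counting peaks within 1 kb as overlapping, H3K4me3 gained 450, 1811 and 2021 on days 1, 3 and 7 and lost 607 by day 7. Requiring overlap of 50% of the island, H3K27me3 lost 5029 by day 7. Thinning to equal depth left 770 H3K27Ac and 6109 H3K27me3 islands lost on day 1, and for H3K4me 6181 gained and 6446 lost, nearer to each other than as listed.

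Shares moved with the stricter list and the stricter overlap. Requiring more overlap can only lower a share. The stricter list also drops weaker regions of the overlapped mark, so islands at weaker H3K4me3 peaks count as distal. How much of each move this explains was not tested. The pairs of days printed here kept their order, but others did not: H3K27Ac islands with H3K4me were most frequent on day 7 as listed, on day 0 with the stricter list and on day 3 with the stricter overlap. With overlap of 50% of the peak, H3K4me3 peaks with H3K4me were 41.2% on day 0 and 24.2% on day 1, and with H3K27Ac 52.0% on day 0 and 74.0% on day 7. In the stricter 50% of each library they were 41.5% and 24.1% with H3K4me, and 33.2% and 54.8% with H3K27Ac. H3K27Ac islands with H3K4me on day 7 were 71.0% with the stricter overlap and 66.7% with the stricter list. With the stricter list, the share of H3K27Ac away from H3K4me3 peaks was 35.7% on day 0 and 42.5% on day 7, and on day 7 50.7% of gained and 27.02% of kept islands lay away from peaks.

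Signal depended on the scaling. Both scalings move all regions alike and the median ratio centres them by construction, so the changes of sign do not show that a direction is undecided. With it the median log2 ratio on days 1, 3 and 7 was -0.013, -0.045 and -0.042 for H3K27Ac, 0.058, -0.18 and -0.19 for H3K27me3, and 0.0090 on day 1 for H3K4me. Scaling by the top 10% of regions gave -0.089, -0.25 and -0.26 for H3K27Ac, 0.17, -0.28 and -0.27 for H3K27me3, and 0.012, 0.037 and 0.023 for H3K4me. Regions 2-fold higher and lower on day 7 were 416 and 464 for H3K27Ac and 762 and 1190 for H3K27me3 by the median ratio, and 258 and 845, and 630 and 1446, by the top 10%. Read density at islands with 80% reciprocal overlap, of which there are fewer, gave 502 higher and 2 lower for H3K27Ac, 193 and 135 for H3K4me, and 23 and 0 for H3K27me3 on day 7. It gave a median log2 ratio of 0.25 for H3K27me3 on day 1. With a depth from the mark's own matched islands, 288 H3K27me3 regions were 2-fold lower on day 7. The depth of the H3K4me3 libraries is unknown, so the effect of depth on their peaks was not tested.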

Other observations

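The tests of H3K4me at new distal H3K27Ac islands and the reverse, of chromosome X and of 1 Mb windows were chosen after the data had been seen. Of 3960 distal H3K27Ac islands of day 7 that had no H3K27Ac on days 0 and 1, 43.9% (42.4% to 45.5%) overlapped an H3K4me island on day 0, 64.9% (63.4% to 66.4%) on day 1, 92.2% (91.3% to 93.0%) on day 3 and 94.1% (93.3% to 94.8%) on day 7. Random shifts gave 7.18%, 6.17%, 9.03% and 9.31%. In the reverse test, of 10131 distal H3K4me islands of day 7 absent on days 0 and 1, 0.168% (0.0978% to 0.269%) overlapped H3K27Ac on day 0, 1.58% (1.35% to 1.84%) on day 1, 10.5% (9.89% to 11.1%) on day 3 and 10.2% (9.58% to 10.8%) on day 7, with 2.41%, 3.65%, 4.92% and 4.55% after random shifts. Each set was picked for lacking its own mark on days 0 and 1, and H3K4me islands exceed H3K27Ac islands in number on every day, so which mark came first is left open. At matched islands the log2 ratio over control of H3K27Ac was 0.72 higher on day 7 than on day 0, and a weaker day 0 library also stays open.

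H3K27me3 islands on chromosome X stood apart from those of the other chromosomes. They numbered 14 on day 0, 7 on day 1, 134 on day 3 and 146 on day 7, a day 7 ratio of 10.4, where the median over 23 chromosomes was 2.31 and chromosome 8 followed with 2.62. H3K27Ac on chromosome X had 98, 168, 310 and 299 islands, a day 7 ratio of 3.05 against a median of 1.84. This chromosome was picked after its values were seen.

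The counts of islands per 1 Mb window were not set against chance or against the density of all islands. The window with the most H3K27Ac islands gained by day 7 was on chromosome 11, 12000001 to 13000000, with 26 against a mean of 3.24 per window. For H3K27me3 it was on chromosome 9, 7000001 to 8000000, with 51 against a mean of 8.18. The window on chromosome 2 from 150000001 to 151000000 held 17 gained H3K4me3 peaks against a mean of 1.01, and the window on chromosome 9 from 139000001 to 140000000 led in lost H3K27Ac islands, with 9 against a mean of 0.299.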
